A study of Arabidopsis thaliana with 6 samples.

How the data were processed

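RNA from 10-day-old Arabidopsis thaliana seedlings was measured on 6 Affymetrix Arabidopsis arrays, each hybridised with biotin-labelled material in 1 colour. Per the labels the arrays fall into 3 groups of 2 biological replicates: wild type, seedlings overexpressing OsTOP6A3 and seedlings overexpressing OsTOP6B. The deposited values are 1 intensity per probe set and array, on a linear scale and never negative. The authors' method for summarising the probes of a set, and any scaling between arrays, are not given in the sources used here. The medians of the deposited intensities differ between arrays, so the columns are not on a common scale. All columns were assigned to an array, and the number left unassigned was 0.

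Of 22810 probe sets on the array, 64 control probe sets were set aside, which left 22746. A pseudocount of 16 was added and the values were turned into log2. Quartiles of the columns differed by up to 0.54 on the log2 scale, more than the limit of 0.1 chosen for leaving them as deposited, and the columns were quantile normalized. A probe set was tested when its mean over the 6 arrays was at or above the 25th percentile. This kept 17059 probe sets and left out 5687. The pseudocount shrinks the fold changes of weakly expressed genes, and a value of 0 becomes 4 on the log2 scale.

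Probe sets were named from the probe table that came with the array type, checked against gene names of assembly TAIR10.1, which was used for names only. Exactly 1 gene was named for 13513 probe sets, of which 13502 had a locus in the assembly; 503 probe sets had several genes and 8730 had none. Of the tested probe sets 9435 had exactly 1 gene. Counts over the array include all tested probe sets, whereas named genes come only from probe sets with exactly 1 gene. Several tested probe sets were present for 106 genes. In 0 of these were probe sets called in opposite directions, and in 19 some probe sets passed and others did not.

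All 6 arrays were fitted together with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with a mean for each group, no intensity trend and no robust option. The fit had 3 residual degrees of freedom and 4.61 prior degrees of freedom. Contrasts compared OsTOP6A3 overexpressors with wild type, OsTOP6B overexpressors with wild type, both kinds of overexpressor with each other, and the mean of both with wild type. The moderated test is two-sided, and p values were adjusted by the Benjamini-Hochberg method over the tested probe sets of each contrast. A probe set was called when its adjusted p was under 0.05. Standard errors given with fold changes are limma's moderated values on the log2 scale. Replicate numbers were not used as a block. The number of arrays limits the precision, and the same 2 wild-type arrays stand in both comparisons with wild type.

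Genes named in the text followed a rule. For each overexpressor it took the 12 largest rises and 12 largest falls among called probe sets with 1 gene whose arrays did not overlap between groups. For the remaining contrasts it took 5 and 5. Where fewer than 5 passed, the smallest unadjusted p with at least a 2-fold change filled the places, and such genes are said not to have passed. Up to 4 members of each gene list, all members of the topoisomerase VI list and the 10 largest changes shared by both overexpressors were added. The normalization rule, filter, tests, lists, naming rule and most alternatives were chosen before the data were examined.

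The 20 gene lists hold 336 genes, of which 51 have a probe set with exactly 1 gene named, so the lists are thinly covered. A gene with several probe sets was represented by the one with the highest mean. For the 6 lists with at least 3 tested members, camera was run with a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists within a comparison. For the 20 lists, but not for the groups added later, counts adjusted over the list alone are given beside those adjusted over all probe sets. In a list with 1 tested member this adjustment leaves p as it was. The groups of plastid-encoded, mitochondrion-encoded and NLR genes (nucleotide-binding leucine-rich-repeat resistance genes) were added after the data had been seen and were adjusted among themselves.

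The overlap of both comparisons with wild type was set beside 50 simulations of unchanged groups sharing 2 controls, and was repeated with 1 wild-type array for each comparison, an alternative added after the data had been seen. The fit and its calls were also tested on simulated data with 200 changed genes among 17059 in 10 simulations per contrast. They recovered 94.6% to 95.1% of 2-fold and 99.9% to 100% of 4-fold changes, while 6.34% to 7.29% of calls were false. The simulated noise was independent between genes and arrays, and normalization and filter were not rerun. These rates therefore leave out errors shared across an array.

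Alternatives were a replicate block, the deposited scale, median scaling, pseudocounts of 1 and 64, no filter, a filter at the 50th percentile, an intensity trend, robust eBayes, only the groups compared, 2-fold minimums with adjusted or unadjusted p, the mean of all probe sets of a gene, an estimated correlation, and leaving out each array in turn. Median scaling shifted log2 values as planned. It had first been run on linear intensities, and that version is kept as an alternative added after the data had been seen. The control probe sets took no part in the tests. No test used the position of a gene.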

Results

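Transcripts of 10-day-old Arabidopsis thaliana seedlings grown in continuous light on sucrose-containing agar were measured on 6 arrays. There were 2 arrays of wild type, 2 of seedlings overexpressing OsTOP6A3 and 2 of seedlings overexpressing OsTOP6B. These transgenes encode rice subunits of topoisomerase VI, an enzyme that passes one DNA duplex through a break in another. The labels give the ecotype Columbia for 5 of the arrays and no ecotype for wild-type replicate 1. The median deposited intensity was 69.7 and 71.7 in wild type, 95.2 and 90.7 in OsTOP6A3 overexpressors, and 103.5 and 66.2 in OsTOP6B overexpressors. Across probe sets, which are not independent replicates, replicate arrays correlated with Pearson's r of 0.988 for wild type, 0.991 for OsTOP6A3 and 0.985 for OsTOP6B. OsTOP6B replicate 1 correlated more with the OsTOP6A3 arrays, at 0.990 and 0.990, than with OsTOP6B replicate 2. Wild-type arrays correlated with overexpressor arrays at 0.966 to 0.974. All folds below are group differences with n = 2 arrays per group, and each error is a standard error on the log2 scale. Folds and orders of genes by size of change hold for the pseudocount of 16 and differ with another, since many of these genes are near background in a group.

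The comparison of OsTOP6A3 overexpressors with wild type asks which transcripts differ in seedlings that overexpress this A subunit. The largest rise at this pseudocount was that of AT2G25510, by 5.07 ± 0.93 on the log2 scale or 33.6-fold, with a limma adjusted p of 0.0154. ECS1, which encodes a cell wall-associated protein, rose by 4.71 ± 0.49 or 26.2-fold, and AT1G23960 rose by 4.42 ± 0.20 or 21.4-fold. The largest fall at this pseudocount was that of AT5G04380, a methyltransferase gene of the SABATH family, at -3.97 ± 0.20 or 15.6-fold lower. AT3G48640 followed at -3.91 ± 0.18 or 15.0-fold lower. EXPA8, an expansin gene, fell by 2.74 ± 0.22 on the log2 scale or 6.66-fold, with an adjusted p of 0.000467.

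Further rises in OsTOP6A3 overexpressors ran from 15.5-fold to 8.56-fold. They included ZW9, a TRAF-like gene, at 3.95 ± 0.23, and M17, of the late embryogenesis abundant type, at 3.53 ± 0.27. AT2G04050, a MATE efflux gene, rose by 3.17 ± 0.31, and the cytochrome P450 gene CYP71B34 rose 8.56-fold. AT3G43740 rose 13.4-fold, AT5G45500 12.9-fold, AT2G43535 11.96-fold, AT2G14460 10.3-fold and AT3G44430 9.21-fold. These folds over a wild type near background move with the pseudocount: the log2 change of AT3G43740 ran from 2.23 with 64 to 5.85 with 1, and that of AT3G44430 from 1.73 to 5.45. Further falls ran from 8.60-fold for AT5G15360 to 4.61-fold for AT5G38020, another SABATH methyltransferase gene. Between them stood AT2G35820 at 6.27-fold, the subtilase gene AT4G21650 at 6.12-fold, the legume lectin gene AT5G03350 at 5.94-fold, the lipid transfer family gene AT5G55450 at 5.90-fold, AT3G28270 at 5.72-fold, AT5G55570 at 5.45-fold and AT4G19470 at 5.38-fold.

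In all, 1652 of 17059 probe sets were called for OsTOP6A3, 941 higher and 711 lower than wild type. Of these, 385 rose and 185 fell at least 2-fold, and 70 rose and 33 fell at least 4-fold. On the deposited scale the median of all changes lay at 0.34 on the log2 scale, and 92.1% of calls were rises, against 57.0% after quantile normalization, so the balance of rises and falls rests on the scaling. Fewer probe sets were called when any of the contributing arrays was left out: 708 without wild-type replicate 1, 870 without wild-type replicate 2, 560 without OsTOP6A3 replicate 1 and 689 without OsTOP6A3 replicate 2.

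The wild-type arrays differed from each other for AT2G25510 and ECS1, the genes with the largest rises at this pseudocount. For AT2G25510 the rise in OsTOP6A3 overexpressors was 6.90 on the log2 scale without wild-type replicate 1 and 3.26 without wild-type replicate 2, and for ECS1 it was 5.62 and 3.85. Wild-type replicate 2 read 4.81 for AT2G25510 and 4.68 for ECS1, near the floor of 4, so changes against it alone depend on the pseudocount. The call of AT2G25510 in OsTOP6A3 overexpressors was lost without OsTOP6A3 replicate 1 (adjusted p = 0.0647) and without OsTOP6A3 replicate 2 (adjusted p = 0.0588). With OsTOP6B it was lost without OsTOP6B replicate 1 (adjusted p = 0.0609, log2 change 4.98) and without OsTOP6B replicate 2 (adjusted p = 0.0655, log2 change 5.28). The fall of AT5G15360 in OsTOP6A3 overexpressors was -2.47 without OsTOP6A3 replicate 1 and -3.70 without OsTOP6A3 replicate 2.

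The comparison of OsTOP6B overexpressors with wild type asks the same of the B subunit. AT2G25510 again showed the largest rise at this pseudocount, 5.12 ± 0.93 on the log2 scale or 34.7-fold, with a limma adjusted p of 0.0117. ECS1 rose by 4.39 ± 0.49 or 20.9-fold, AT1G23960 by 4.34 ± 0.20 or 20.3-fold, and AT5G45500 by 3.92 ± 0.24 or 15.1-fold. The largest fall at this pseudocount was again that of AT5G04380, at -4.23 ± 0.20 or 18.8-fold lower, and AT3G48640 changed by -3.56 ± 0.18 or 11.8-fold lower. AT5G55450 changed by -3.01 ± 0.17, 8.06-fold lower than wild type.

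Other named rises in OsTOP6B overexpressors were ZW9 at 14.6-fold, AT3G43740 at 14.2-fold, M17 at 13.5-fold, AT2G43535 at 12.3-fold, AT2G14460 at 11.02-fold, CYP71B34 at 10.8-fold, AT2G04050 at 9.10-fold and AT1G65370, a TRAF-like gene, at 8.56-fold. Other named falls were AT2G35820 at 7.19-fold, AT5G15360 at 7.04-fold, AT4G19470 at 6.97-fold, AT5G55570 at 6.94-fold, AT3G28270 at 6.02-fold, AT5G03350 at 5.98-fold, EXPA8 at 5.46-fold, AT4G21650 at 5.31-fold and AT5G38020 at 5.14-fold. ECS1 rose by 5.29 without wild-type replicate 1 and by 3.52 without wild-type replicate 2, and AT2G25510 rose 9.88-fold without wild-type replicate 2 and by 6.94 on the log2 scale, against a wild-type value near the floor, without wild-type replicate 1. The call of AT5G15360 was lost with a pseudocount of 1 (adjusted p = 0.0652).

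For OsTOP6B, 2540 probe sets were called, 1350 higher and 1190 lower. At least 2-fold changes were 451 rises and 242 falls, and at least 4-fold changes were 82 rises and 35 falls. Without scaling, the median of all changes was 0.18 on the log2 scale, 1460 probe sets were called and 84.5% of these were rises, against 53.1% after normalization. Without wild-type replicate 1 there were 1054 calls and without wild-type replicate 2 there were 1251.

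**Figure D1:**
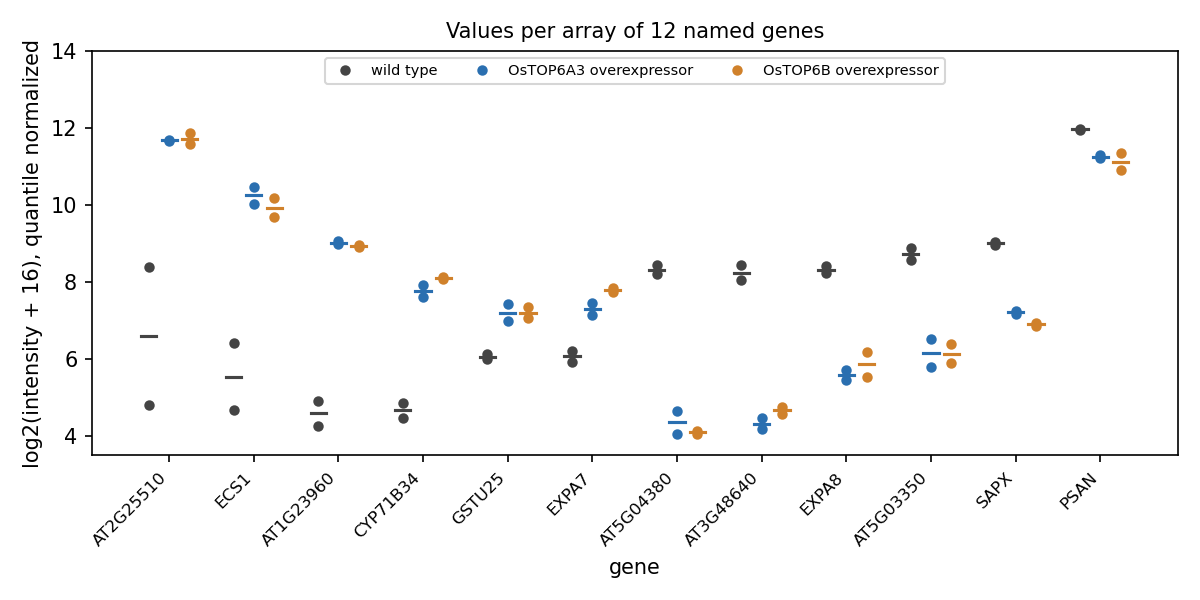
Normalized log2 intensity (y axis) of 12 named genes (x axis) in the 3 groups (colours), with a dot for each array and a line at each group mean. For AT2G25510 and ECS1 the wild-type arrays lie far apart, while the change of AT5G04380, by -3.97 in OsTOP6A3 and -4.23 in OsTOP6B overexpressors, exceeds the distance between replicates.

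In the antioxidant list, of which 3 of 21 members were measured, SAPX fell and GSTU25 rose in both lines. SAPX, which encodes a stromal ascorbate peroxidase of the chloroplast, changed by -1.78 ± 0.12 with OsTOP6A3 (3.44-fold, adjusted p = 0.000267) and by -2.10 ± 0.12 with OsTOP6B (4.28-fold, adjusted p = 0.00012). TAPX, the thylakoid ascorbate peroxidase gene, fell with OsTOP6B, at -0.77 ± 0.14, and its OsTOP6A3 value of -0.51 ± 0.14 did not pass (adjusted p = 0.0704). On the deposited scale the OsTOP6B value of TAPX was -0.52 and its call was lost (adjusted p = 0.280). GSTU25, a glutathione transferase gene, rose by 1.15 ± 0.18 with OsTOP6A3 and by 1.15 ± 0.18 with OsTOP6B. Of 3 measured members of the antioxidant list, 1 rose and 1 fell with OsTOP6A3 (adjusted over the list alone, 1 and 2), and 1 rose and 2 fell with OsTOP6B (adjusted over the list alone, 1 and 2). The list as a whole did not pass in camera, with adjusted p of 0.318 and 0.350. The call of TAPX was lost without wild-type replicate 1 (adjusted p = 0.0828) and without OsTOP6B replicate 2 (adjusted p = 0.0512), and that of GSTU25 with OsTOP6A3 was lost without wild-type replicate 1 (adjusted p = 0.0563).

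Among 7 measured photosynthesis genes, 1 rose and 1 fell in each line, and the same counts held adjusted over the list alone. LHCB4.2, a light-harvesting protein gene, rose by 0.72 ± 0.16 with OsTOP6A3 (adjusted p = 0.0344) and by 0.79 ± 0.16 with OsTOP6B (adjusted p = 0.0193). PSAN, a photosystem I subunit gene, changed by -0.71 ± 0.16 (adjusted p = 0.0327) and by -0.83 ± 0.16 (adjusted p = 0.0141). On the deposited scale PSAN lost both calls, at -0.35 (adjusted p = 0.394) and -0.69 (adjusted p = 0.106). LHCB4.1, PSAE-1, RCA, PRK and SBPASE did not pass in either line, and camera gave adjusted p of 0.402 and 0.350. The OsTOP6A3 calls were lost without any one of wild-type replicate 1, wild-type replicate 2, OsTOP6A3 replicate 1 and OsTOP6A3 replicate 2, with adjusted p of 0.149, 0.104, 0.183 and 0.124 for LHCB4.2 and of 0.135, 0.121, 0.179 and 0.117 for PSAN. With OsTOP6B both calls were lost without wild-type replicate 1 (adjusted p = 0.0923 for LHCB4.2 and 0.0713 for PSAN) and without wild-type replicate 2 (0.0683 and 0.0677), and that of LHCB4.2 also without OsTOP6B replicate 2 (0.0508).

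Root-hair expansin genes rose, EXPA7 in both lines and EXPA18 with OsTOP6B. EXPA7 rose by 1.23 ± 0.16 with OsTOP6A3 (adjusted p = 0.00357) and by 1.73 ± 0.16 with OsTOP6B (adjusted p = 0.00077). EXPA18 rose by 0.81 ± 0.15 with OsTOP6B, and its value with OsTOP6A3 was 0.15 ± 0.15. PYK10, a root beta-glucosidase gene, had values of 0.16 and 0.15 and did not pass. Of the 3 measured root markers 1 rose with OsTOP6A3 and 2 with OsTOP6B, with the same numbers adjusted over the list alone. As a list they passed in camera with OsTOP6B (adjusted p = 0.0348) and did not pass with OsTOP6A3 (adjusted p = 0.307). The OsTOP6B list call was lost at adjusted p = 0.412 with an estimated correlation, and also with median scaling of linear intensities. EXPA18 lost its call without wild-type replicate 1 (adjusted p = 0.0826).

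The cell division genes TOPII and AUR2 fell with OsTOP6B. TOPII, which encodes topoisomerase II, changed by -0.47 ± 0.13 (adjusted p = 0.047) and AUR2, an Aurora kinase gene, by -0.56 ± 0.13 (adjusted p = 0.0324). With OsTOP6A3 their values were -0.17 and -0.43 and did not pass, although AUR2 fell adjusted over the list alone. In the S-phase list PRL had 0.15 and 0.30, and in the mitosis list AUR1 had -0.05 and 0.07. Thus 1 of 2 members fell with OsTOP6B in each of these lists, also adjusted over the list alone. With replicate numbers as a block the TOPII call was lost (adjusted p = 0.0681). Both calls were lost on the deposited scale, with adjusted p of 0.696 for TOPII and 0.563 for AUR2. Both were also lost when any single array of the 6 was left out, with adjusted p from 0.0816 (without OsTOP6B replicate 2) to 0.204 (without wild-type replicate 2) for TOPII and from 0.0529 (without OsTOP6A3 replicate 1) to 0.128 (without wild-type replicate 2) for AUR2.

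Of 6 genes in the topoisomerase VI list 2 were tested, SPO11-2 and BIN4, and neither gave a call. The other members, apart from ATSPO11-1, had no probe set with exactly 1 gene named and were not measured. SPO11-2 had log2 changes of 0.06 ± 0.33 with OsTOP6A3 and -0.35 ± 0.33 with OsTOP6B, and BIN4, which encodes a part of the plant topoisomerase VI complex, had -0.37 ± 0.27 and -0.00 ± 0.27. Adjusted over the list alone the count was 0 as well, and ATSPO11-1 lay under the filter with a mean log2 of 4.82. SIM, a cell-cycle inhibitor gene in the endoreduplication list with BIN4, had -0.34 and -0.35, with 0 of 2 members passing, also adjusted over the list alone. In the DNA damage list ATLIG4 had -0.23 and -0.14 and AT4G32700 had -0.27 and -0.53, with 0 of 2 called and 1 lower with OsTOP6B adjusted over the list alone.

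Stress and hormone lists held few called genes. GRX480, a glutaredoxin gene of the salicylate list, fell with OsTOP6A3 by 0.94 ± 0.20 (adjusted p = 0.0273) and had -0.65 ± 0.20 with OsTOP6B, which did not pass (adjusted p = 0.0688) but was 1 fall adjusted over the list alone; WRKY53 and SAG101 did not pass, and camera gave adjusted p of 0.318 and 0.840. The GRX480 call was lost without wild-type replicate 1 (0.140), wild-type replicate 2 (adjusted p = 0.054), OsTOP6A3 replicate 1 (0.132) or OsTOP6A3 replicate 2 (0.107). Of 5 cold-regulated genes the dehydrin gene COR47 fell with OsTOP6B by 0.65 ± 0.14 (adjusted p = 0.0206), a call lost without wild-type replicate 1 (adjusted p = 0.111), wild-type replicate 2 (0.0636) or OsTOP6B replicate 1 (0.0573). With OsTOP6A3 none of the 5 passed, COR47 having -0.45 and COR15B 0.41, while 1 rose and 1 fell adjusted over the list alone; with OsTOP6B that count was 1 fall, and camera gave adjusted p of 0.986 and 0.840. Of 2 heat-shock genes AT5G51440 had 0.57 ± 0.20 and 0.73 ± 0.20 (adjusted p = 0.125 and 0.0509), which was 1 rise adjusted over the list alone in each line, and AT5G37670 had -0.30 and -0.13.

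In the jasmonate list PDF1.2 had 0.24 and 0.80 and PDF1.2b 0.07 and 0.55, none passing, and STZ, the only measured member of the touch list, had -0.22 and 0.02. Adjusted over the list alone both lists stayed at 0. EXPA8 was the only measured member of the brassinosteroid list and fell in both lines, also adjusted over the list alone. None of 3 auxin-response genes passed, with IAA29 at -0.68 and -0.42, 0 adjusted over the list alone, and camera adjusted p of 0.318 and 0.350. In the anthocyanin list DFR had 0.06 and 0.36 and UF3GT 0.85 and 0.58, with 1 rise with OsTOP6A3 adjusted over the list alone. GI, the only measured clock gene, had -0.61 ± 0.18 with OsTOP6A3 (adjusted p = 0.0803, 1 fall adjusted over the list alone) and -0.15 with OsTOP6B. The abscisic acid list had 1 gene on the array and 0 tested, and the seed and flower-transition lists had 0 genes with a probe set.

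Comparing the lines with each other asks whether the overexpressors differ. The labels give a single name for the arrays of each overexpressor and no vector control. An effect of the subunit therefore cannot be told apart from one of the line used. The 5 genes taken in each direction did not pass, and the 5 with OsTOP6A3 below OsTOP6B were plastid-encoded. The ribosomal protein gene rpl16 differed by -1.40 ± 0.19 (adjusted p = 0.505), ndhE by -1.46 ± 0.25 (0.642), accD by -1.34 ± 0.27 (0.663), rps15 by -1.13 ± 0.23 (0.658), and psbA, which encodes the D1 protein of photosystem II, by -1.06 ± 0.21 (0.657). In the other direction AT4G28703 differed by 1.15 ± 0.12 (adjusted p = 0.251), AT5G62210 by 1.02 ± 0.18 (0.642), AT5G07740 by 1.11 ± 0.20 (0.642), AT5G15780 by 1.15 ± 0.34 (0.675) and AT1G01840 by 1.09 ± 0.34 (0.675).

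In limma 0 of 17059 probe sets passed between the lines, 1235 had an unadjusted p under 0.05, and 26 of these differed at least 2-fold, 9 higher and 17 lower in OsTOP6A3. The median 95% interval of a difference reached 0.34 on the log2 scale to either side, or 1.27-fold. This interval is not adjusted for the number of probe sets, and the number of arrays limits which differences can pass. The 25S ribosomal RNA control read 315 in OsTOP6B replicate 1 and 46.7 in OsTOP6B replicate 2, a difference that goes with the higher plastid-encoded values of the former. Root markers were lower in OsTOP6A3 as a list in camera, by a median of -0.50 (adjusted p = 0.0283). This list call was lost at adjusted p = 0.354 with an estimated correlation, and also with median scaling of linear intensities. EXPA18 differed by -0.66 and EXPA7 by -0.50, neither passing over all probe sets, while 2 were lower adjusted over the list alone. GI, the only tested member of its list, differed by -0.46 and did not pass over all probe sets (limma adjusted p = 0.677). Its unadjusted p was under 0.05, which is all that adjustment over a list of 1 gene asks. In the other fixed lists 0 members passed between the lines, also adjusted over the list alone.

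The mean of both lines against wild type asks for the average change over the lines, which a change in a single line can carry. EXPA18, for example, was called in this mean at 0.48, with 0.15 in OsTOP6A3 and 0.81 in OsTOP6B overexpressors. AT2G25510 rose by 5.09 ± 0.81 or 34.1-fold (limma adjusted p = 0.0057), ECS1 by 4.55 ± 0.42 or 23.4-fold, AT1G23960 by 4.38 ± 0.18 or 20.8-fold, ZW9 by 3.91 ± 0.20 or 15.0-fold and AT5G45500 by 3.80 ± 0.20 or 13.95-fold. AT5G04380 changed by -4.10 ± 0.18 or 17.1-fold lower, AT3G48640 by -3.74 ± 0.15 or 13.3-fold lower, AT5G15360 by -2.96 ± 0.32, AT5G55450 by -2.79 ± 0.15 and AT2G35820 by -2.75 ± 0.18. AT3G43740, M17 and AT2G43535, at 3.79, 3.64 and 3.60, complete the 10 largest shared changes. The heat-shock gene AT5G51440 rose by 0.65 (adjusted p = 0.0423). AT2G25510 rose by 6.92 without wild-type replicate 1 and by 3.28 without wild-type replicate 2, and ECS1 by 5.46 and 3.68.

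For the mean of both, 2924 probe sets were called, 1548 higher and 1376 lower, with 408 rises and 187 falls of at least 2-fold and 78 rises and 29 falls of at least 4-fold. There were 1149 calls without wild-type replicate 1, 1371 without wild-type replicate 2, 1616 without OsTOP6A3 replicate 1 and 1821 without OsTOP6A3 replicate 2. On the deposited scale the median of all changes was 0.26 on the log2 scale, and 2172 probe sets were called higher and 232 lower. Among fixed lists, 1 antioxidant gene rose and 2 fell, 1 photosynthesis gene rose and 1 fell, 2 root markers rose, and COR47, GRX480, AUR2 and EXPA8 fell, while no list passed in camera, the lowest adjusted p being 0.0722 for root markers. Adjusted over the list alone these stayed and TOPII, SIM and GI fell and UF3GT rose. None of the added genes passed over all probe sets, with limma adjusted p of 0.0889, 0.0799, 0.141 and 0.0862 in that order. Their lists had only 1 or 2 tested members.

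The changes with OsTOP6A3 and OsTOP6B were compared across probe sets. AT1G23960, ZW9 and CYP71B34 rose and AT5G04380, AT3G48640 and SAPX fell in both. Calls in the same direction numbered 824 rises and 546 falls, together 1370, which is 82.9% of OsTOP6A3 calls and 53.9% of OsTOP6B calls, and 0 probe sets were called in opposite directions. On the deposited scale, whose median shift favours rises, the shared calls were 1070 rises and 124 falls. Independent lists would share 74.5 rises and 49.6 falls. Both comparisons subtract the same wild-type arrays, however, so their calls are not independent. These expected numbers therefore cannot decide how far the overlap exceeds that from shared controls. The shared arrays also favour calls in the same direction, so the lack of opposite calls cannot decide it either. At least 4-fold changes in both lines were found for 94 probe sets, 66 rises and 28 falls.

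Log2 changes of both lines correlated across probe sets with Pearson's r of 0.895, against at most 0.512 in 50 simulations of unchanged groups that share their controls, and genes are not independent replicates. The covariance was 0.193 against 0.0139 in the simulations. With a wild-type array of its own for each line, a division chosen after the data had been seen, r was 0.738 with OsTOP6A3 against wild-type replicate 1 and 0.767 with OsTOP6A3 against wild-type replicate 2. The covariances of these divisions were 0.174 and 0.178. Shared calls fell to 623 without wild-type replicate 1, 766 without wild-type replicate 2, 524 without OsTOP6A3 replicate 1 and 630 without OsTOP6A3 replicate 2.

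**Figure D2:**
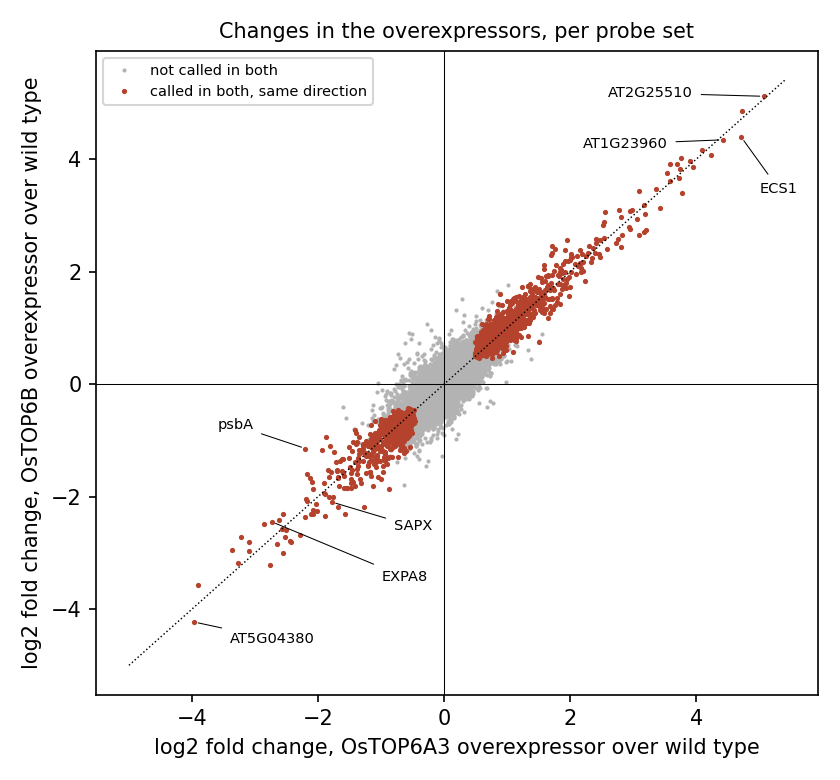
Log2 fold change against wild type with OsTOP6A3 (x axis) and OsTOP6B (y axis), with a point for each of 17059 tested probe sets and names at selected genes. Points lie along a rising line, with r of 0.895 across probe sets, and share the same 2 wild-type arrays on both axes.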

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

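The tests of plastid transcripts against single OsTOP6B arrays and with median scaling of linear intensities were chosen only after the result was seen, as were the organelle gene groups themselves.

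Plastid-encoded transcripts differed between the lines as a group: 51 of 68 were lower in OsTOP6A3 than in OsTOP6B, with a median of -0.40 on the log2 scale (camera adjusted p = 1.99e-15, but adjusted p = 0.285 with an estimated correlation). Against a difference in array brightness as the whole source, the median relative to all probe sets was still -0.36 on the deposited scale, a value that median scaling of log2 values leaves as it is, and -0.38 with median scaling of linear intensities. More RNA without a poly(A) tail labelled in OsTOP6B replicate 1 remains a possible explanation and cannot be told apart from a difference between the lines, because against OsTOP6B replicate 2 alone the median was -0.13 and against replicate 1 it was -0.63, each from a single OsTOP6B array with no measure of the variation between arrays. Mitochondrial transcripts, 8 genes that would share such a source, had medians of 0.01 against replicate 1 and -0.20 against replicate 2. Most of these genes read low in wild type, such as cox2 at 5.02 and nad1 at 5.27 with a floor of 4. Their medians therefore cannot decide for or against it. An effect of the transgene subunit on plastid transcripts was not tested apart from these arrays.

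Root-tissue markers had a median difference between the lines of -0.50 over 3 genes, of which 0 passed on their own (camera adjusted p = 0.0283, adjusted p = 0.354 with an estimated correlation). Their list call was also lost with median scaling of linear intensities. Mitochondrion-encoded genes had a median of -0.17 over 8 genes (camera adjusted p = 0.0424, adjusted p = 0.324 with an estimated correlation). One control probe set outside the comparisons, whose target is not given, read 3.1 and 19.2 in wild type against 496.7 and 484.0 in OsTOP6A3 and 323.7 and 365.0 in OsTOP6B overexpressors. The control probe set for 25S ribosomal RNA read 315 in OsTOP6B replicate 1, 46.7 in OsTOP6B replicate 2, and 23.9 and 53.7 in wild type. The same array read 600.6 for the dap spike-in control, against 213.3 to 321.4 elsewhere. It was also the highest for the lys, phe and thr controls, with 239.8 for thr against 99.5 to 148 elsewhere. For the bioD control it read 1493.5, within the 829.6 to 1850.9 of the other arrays.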

How the results depend on the processing

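Of the tests in this part, median scaling of the linear intensities and those of the plastid group were chosen only after results were seen. Of 77 called results of named genes, 63 kept direction and call under every alternative that gave a value. Of 1271 gene and alternative pairs, 65 lost the call and 0 reversed. Most of the 77 were picked as the largest changes, which favours keeping a call. Among called list genes, SAPX, EXPA7 and EXPA8 in both lines and GSTU25 with OsTOP6B kept it throughout. The other called list genes lost it in some alternative. Among 66 uncalled results, 47 pairs changed sign. The count for OsTOP6A3 was 1100 with a pseudocount of 1 and 1002 without a filter, and that for OsTOP6B was 1460 on the deposited scale and 1608 without a filter, where more probe sets are tested. Named calls were lost on the deposited scale for GRX480 and PSAN with OsTOP6A3 and for COR47, TAPX, TOPII, AUR2 and PSAN with OsTOP6B; with a pseudocount of 1 for AT2G25510 in both lines (adjusted p = 0.0725 and 0.0561), for AT5G15360 and TOPII with OsTOP6B and for GRX480, LHCB4.2 and PSAN with OsTOP6A3; and without a filter for AT2G25510 (0.0525), GRX480, LHCB4.2 and PSAN with OsTOP6A3 and TOPII and AUR2 with OsTOP6B. TOPII kept its call in few settings, losing it in 13 of 17, with adjusted p from 0.0221 to 0.696. Between the lines 5 passed on the deposited scale, 1 with a pseudocount of 64 and 1 with an intensity trend, and 26 with an unadjusted p and 2-fold. A 2-fold minimum with adjusted p left 570 for OsTOP6A3, 693 for OsTOP6B and 595 for the mean of both, which follows from the added criterion; with unadjusted p these were 591, 702 and 601. Shared calls were 867 without a filter. The list calls, 2 at first, were both for root markers, with OsTOP6B against wild type and between the lines. List calls numbered 1 on the deposited scale, 1 with median scaling and 0 with median scaling of linear intensities. They numbered 1 without a filter and 0 with an estimated correlation. Where the construction does not show it, the cause was not tested. Leaving out each array in turn, where the lone array of a group is assumed to vary like the other groups, gave 560 to 2017 for OsTOP6A3, 1054 to 2210 for OsTOP6B, 1149 to 3048 for the mean of both, 524 to 1285 shared calls, 0 to 3 list calls and 0 throughout between the lines. The lowest counts came without OsTOP6A3 replicate 1 (560 and 524) and without wild-type replicate 1 (1054 and 1149), and without OsTOP6B replicate 1 list calls were 0. The plastid median was -0.13 without OsTOP6B replicate 1 and -0.63 without OsTOP6B replicate 2. Replicate numbers used as a block gave 1452, 2161, 0 and 2588 calls, 1205 shared calls and 2 list calls; correlations of residuals over the numbers, 0.00, -0.05 and 0.02, show no pairing. The comparison of the mean of both uses all arrays, so restricting arrays to the groups compared gave no separate value. Signal near background is compressed by the pseudocount: the rise of AT1G23960 with OsTOP6A3 was 5.95 with a pseudocount of 1, where that of AT2G25510 was 5.65, and 2.97 with 64. Genes under the filter of an alternative gave no value there: AT5G04380 with a pseudocount of 1, AT4G19470 without wild-type replicate 1, and, with the filter at the 50th percentile, weak genes such as AT3G48640, AT5G15360 and EXPA8.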

Other observations

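All tests here were chosen only after the result was seen, except the test of array brightness, and the genes named here were picked after their values were seen.

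Resistance genes of the NLR class were among the larger changes in both lines. With OsTOP6A3 12 of 58 tested rose and 2 fell, and with OsTOP6B 14 rose and 3 fell. AT3G44630, of the TIR-NBS-LRR type, rose by 2.95 ± 0.17 and by 2.76 ± 0.17, AT5G40910 by 2.58 ± 0.27 and 2.40 ± 0.27, and AT5G36930 by 2.11 ± 0.17 and 2.11 ± 0.17. AT1G59780 had -1.41 and -1.81 and CW9 -1.12 and -1.21, both falling in both lines. As a group they did not pass with OsTOP6A3 (camera adjusted p = 0.0998) and passed with OsTOP6B (adjusted p = 0.019), the latter lost at adjusted p = 0.217 with an estimated correlation. The median with OsTOP6A3 was -0.04 relative to all probe sets and -0.02 on the deposited scale, while the mean was 0.23. With OsTOP6B these medians were 0.11 and 0.12 and the mean was 0.28. Members went both ways in each line.

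Some organelle genes passed against wild type, where 1652 of all 17059 probe sets were called with OsTOP6A3 and 2540 with OsTOP6B. The plastid gene psbA changed by -2.20 ± 0.21 with OsTOP6A3 and by -1.15 ± 0.21 with OsTOP6B, and rps4 fell with OsTOP6A3, at -1.55 ± 0.18. Of 68 plastid genes 1 rose and 3 fell with OsTOP6A3, and 8 rose and 1 fell with OsTOP6B. As a group they were called lower with OsTOP6A3 (camera adjusted p = 0.0091; adjusted p = 0.580 with an estimated correlation) and higher with OsTOP6B (0.019; adjusted p = 0.658 with an estimated correlation). The OsTOP6B arrays differed in this: the plastid median, as a deviation from the mean of the 6 arrays, was 0.37 in OsTOP6B replicate 1, which also had the high 25S ribosomal RNA reading of 315, and -0.05 in OsTOP6B replicate 2, against 0.12 and -0.07 in wild type. The mitochondrial gene nad1 rose by 1.10 ± 0.17 and by 1.03 ± 0.17, and nad9 rose by 0.59 ± 0.14 with OsTOP6B. Of 8 mitochondrial genes 1 rose with OsTOP6A3 and 2 with OsTOP6B (camera adjusted p = 0.0998 and 0.00814; adjusted p = 0.309 with an estimated correlation for the latter).

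The changes of at least 4-fold shared by both lines were weighed against 3 explanations. On array brightness as their source, the median shift without scaling was 0.34 with OsTOP6A3 and 0.18 with OsTOP6B on the log2 scale. Shifts of this size are small beside a 4-fold change. On the deposited scale and with median scaling, 100% of these 94 probe sets kept both calls and a 2-fold change. With such small shifts the selection nearly fixed the fold part of this outcome in advance, so it adds no support. Against a chance error of 1 wild-type array, probe sets picked for a 4-fold change with OsTOP6A3 against one wild-type array were at least 2-fold changed in the same direction with OsTOP6B against the other in 99.0% (97 of 98) and 100% (112 of 112) of cases. A genetic background of the wild type that differs from that of the lines may contribute: 3 of 53 strongly changed loci were NLR genes against 58 of 9238 tested, an odds ratio of 9.95 (95% interval 1.93 to 32.3, Fisher's exact test, two-sided p = 0.0044). This cannot be told apart from an effect of the transgenes, because the family was picked after its members had been seen and each line is compared with the same wild type, for which 1 label lacks the ecotype.

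With the strongly changed loci left out, 10 of 55 NLR genes were called in both lines against 7.68% of other loci, an odds ratio of 2.67 (95% interval 1.195 to 5.41, Fisher's exact test, two-sided p = 0.00875). The family and the wild-type arrays are the same as above, so this is no separate support. Fisher's exact test also treats loci as independent replicates, which genes are not. By chromosome, strongly changed loci were 14 of 2433 tested on 1, 10 of 1359 on 2, 8 of 1888 on 3, 7 of 1357 on 4 and 14 of 2201 on 5. Of the 94 strongly changed probe sets, 7 differed between the lines at an unadjusted p under 0.05.

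AT2G25510 and ECS1 were brighter in wild-type replicate 1, at log2 values of 8.40 and 6.41, than in wild-type replicate 2, at 4.81 and 4.68. A mixture of transgenic RNA in wild-type replicate 1 could give this, but would raise all strongly risen probe sets alike. Over all 66 of them, these genes included, the median excess was 1.28% of the overexpressor level (interval 0.304 to 2.61 from resampling probe sets, which leaves out variation between arrays), against 5.43% for ECS1 and 9.36% for AT2G25510, and 14 reached the ECS1 value, both genes among them. A difference between the seedlings behind the wild-type arrays was not tested.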
